A study of Mus musculus with 10 samples.

How the data were processed

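Poly(A) RNA of 10 mouse libraries was analysed: 3 scramble, 3 shBRD4, 2 scramble with DMSO and 2 scramble with SGC0946. Groups were taken from the sample titles. The authors deposited 1 table of CPM, reads scaled to a common library size, for 11932 genes by Ensembl identifier, with 10 columns, each of which matched 1 library. Per the submitters' processing notes, TopHat2, Bowtie2, HTSeq and edgeR were used with the mouse genome build mm10. Their versions and settings, the annotation, the strandedness of the libraries and the handling of reads that match several genes are not given in the sources used here. Every deposited CPM value was a whole multiple of the value of 1 read in its column (100.0% within 0.01 read), so reads could be recovered, 10107395 to 12910271 per library over the listed genes. The column sums lay between 985889 and 1009293, and the factors behind them matched trimmed-mean (TMM) factors recomputed from the recovered reads with edgeR. Each listed gene had at least 1 CPM in at least 2 libraries, which shows that low genes had been removed before deposit. Symbols were found for 11867 of the identifiers and coordinates for 11873 in GENCODE release M21 (GRCm38, which is mm10); genes without a symbol were tested but not named.

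All comparisons used limma on log2(CPM + 1), with 1 mean per group over all 10 libraries in 1 model (6 residual degrees of freedom), moderated with a trend on expression. Tests were two-sided and adjusted by the method of Benjamini and Hochberg over the 11932 genes of each comparison, with an adjusted p threshold of 0.05. A filter of at least 1 CPM in at least 2 libraries removed 0 genes. The comparisons were shBRD4 against scramble, SGC0946 against DMSO, the difference of these effects, and DMSO against untreated scramble. Fold changes are log2 values with their standard errors (SE), and group values are mean CPM with the standard deviation (SD). Depth sets the precision: a count of 3 reads corresponds to 0.234 to 0.297 CPM, which covers counting error only.

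Genes named were set by rule: Brd4, Brd2, Brd3, Dot1l, Myc, Hoxa9 and Meis1 in every comparison; the 10 largest rises and the 10 largest falls with the hairpin and with SGC0946 (5 each in the other comparisons) among genes past the threshold, with all libraries of a group above all of the other, at least 5 CPM in the higher group and an established symbol; and up to 4 members of each list by smallest adjusted p. Genes named outside this rule were chosen after their values were seen: the RNA species without poly(A) tails, the families of the last part and the HoxA members drawn by position. Of 47 named genes checked for overlap, 5 (Brd2, Igsf6, Meis1, Pcdh7 and Tnfrsf9) overlap another listed gene, and their reads could be shared. The check covered the genes fixed beforehand and those with the largest changes, not list or family members. Among those not checked, Hoxa3 overlaps Hoxa4, Hoxa5 and Hoxa6, and Hist1h1e overlaps Hist1h2be.

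The 30 gene lists were fixed beforehand: MLL-AF9 and DOT1L targets, MYC targets, stem and progenitor genes, monocyte, neutrophil, dendritic cell, MHC class II, lysosome, DNA replication, mitosis, p53, BCL2 family, BET and elongation complexes, histones, interferon, NF-kB, immediate early, cholesterol, glycolysis, ATF4, oxidative phosphorylation, ribosomal protein, mitochondrially encoded, erythroid, megakaryocyte, mast cell, B cell, T and NK cell, fibroblast and endothelial, and sex-linked genes. The 25 lists with at least 5 measured genes were tested with camera of limma (preset correlation 0.01), and again with an estimated correlation and with fry. Camera compares a list with all other genes, whereas fry asks whether its genes move on balance in a direction.

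The method was tested on simulated data of the same size. For 3 libraries against 3, it recovered 68.0% of genes changed 1.25-fold, 92.0% of those changed 1.5-fold, 96.0% at 2-fold and 100.0% at 4-fold, with 4 false calls among 11686 unchanged genes. For 2 against 2 it recovered 56.0%, 78.0%, 98.0% and 100.0%, with 13 false calls among 11695. The changed list was called in both simulations and 0 of 20 unchanged lists were. Simulated genes varied independently of each other and few were changed. The list result therefore does not cover lists of correlated genes, and the estimated correlation of the real lists reached 0.61.

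The alternatives were pseudocounts of 0.1 and 5 CPM, no filter, a mean of at least 5 CPM (9991 genes), median-of-ratios and quantile scaling, array weights, robust moderation, each pair of groups alone, replicate number as a block, each library left out, other control groups, and the count tests of edgeR and DESeq2 on recovered reads. The edgeR quasi-likelihood test called 9867 genes for the hairpin, 5703 for SGC0946, 6767 between controls and 9031 for the difference. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.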

Results

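The data were messenger RNA levels in mouse bone marrow progenitors of the C57BL/6 strain that carry c-Kit, the receptor for stem cell factor, and had received MLL-AF9, a fusion oncogene of acute leukaemia. A scrambled hairpin or a hairpin against Brd4 had been introduced. BRD4 is a reader of acetylated histones that recruits the elongation machinery. Some cells with the scrambled hairpin had also received DMSO, the vehicle, or SGC0946 at 5 µM, an inhibitor of the histone methyltransferase DOT1L. The 10 libraries formed 4 groups: scramble (n = 3), shBRD4 (n = 3), scramble with DMSO (n = 2) and scramble with SGC0946 (n = 2). The series title also names the Brd4 hairpin combined with the compound, but no library of that kind was among the 10, so the combination was not analysed here.

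The table listed 11932 genes. The scramble libraries held 12910271, 11600039 and 12126056 reads over these genes, and the shBRD4 libraries held 11549824, 12622102 and 11461686. The DMSO libraries held 10797785 and 12073982, and the SGC0946 libraries held 12149038 and 10107395. In each library 1 read was worth between 0.0780 and 0.0990 CPM, reads scaled to a common library size. CPM are relative, so that a gene can rise in CPM without a rise per cell. Fold changes are differences of log2(CPM + 1), which understates the fold of genes near 1 CPM. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these libraries. Across all genes, the correlation of log2 values lay between 0.996 and 0.997 within groups and between 0.926 and 0.932 from scramble to shBRD4. Between scramble and DMSO libraries it lay between 0.977 and 0.982, and between DMSO and SGC0946 libraries between 0.973 and 0.976. The first principal component carried 76.8% of the variance and the second 10.2%.

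Brd4, the target of the hairpin (chromosome 17, 32196274 to 32284722, mm10), stood at 252, 248 and 249 CPM in the scramble libraries and at 77.6, 85.2 and 79.2 CPM in the shBRD4 libraries. It stood at 179 and 189 CPM with DMSO and at 201 and 204 CPM with SGC0946.

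**Figure D1:**
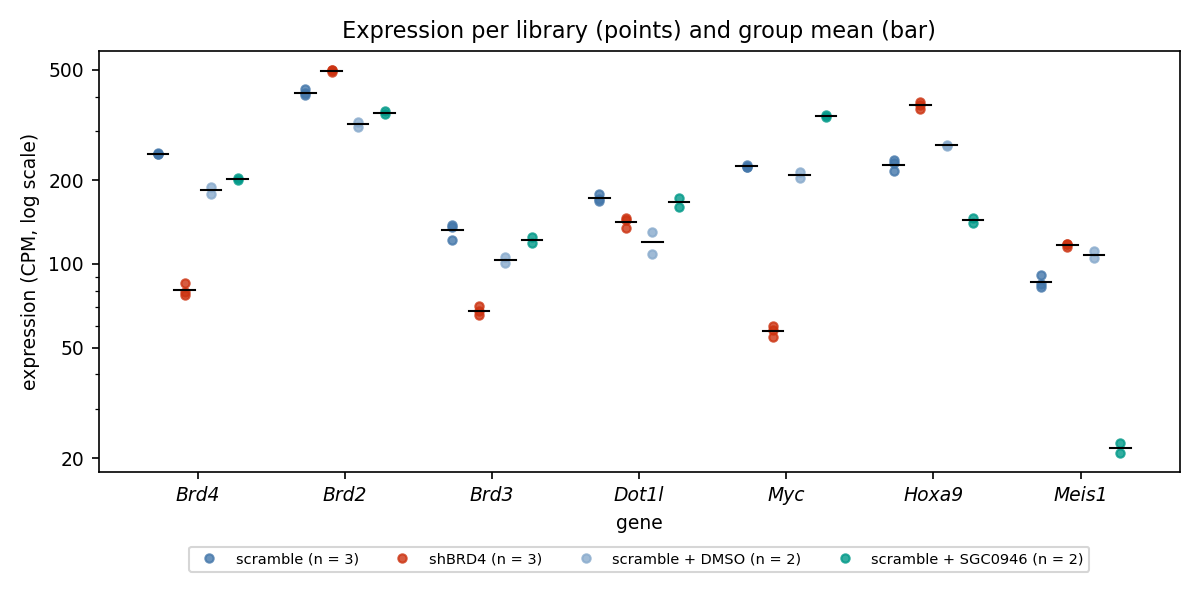
Expression of the 7 genes fixed beforehand, in CPM on a log axis, with a point for each of the 10 libraries and a bar at the mean of each group. Brd4 lay between 77.6 and 85.2 CPM in the shBRD4 libraries and at 179 CPM or more in the other 7 libraries.

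The comparison of shBRD4 with scramble asked which genes depend on BRD4 in these cells. Brd4 fell from 250 ± 2.03 to 80.7 ± 4.03 CPM (SD, n = 3 per group). Myc, the proliferation-driving transcription factor (chromosome 15, 61985391 to 61990374), fell from 225 ± 1.54 to 57.5 ± 2.7 CPM, and all 31 measured genes of the MYC list, which holds Myc itself, fell. All 29 mitosis genes and all 53 cytosolic ribosomal protein genes fell as well. S100a9, a calcium-binding protein of neutrophils and monocytes, had the largest rise, from 14 ± 0.749 to 534 ± 34.2 CPM. In contrast, Hoxa9 and Meis1, the homeobox genes that MLL-AF9 activates, were higher by 0.71 and 0.44 on the log2 scale. The size of the Meis1 rise depends on the control. It stood at 118, 118 and 115 CPM in the shBRD4 libraries and at 111 and 105 CPM in scramble with DMSO. Hoxa9 stood at 363, 382 and 374 CPM in the shBRD4 libraries and at 266 and 269 CPM in scramble with DMSO.

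Of the 11932 genes, 9829 changed with the Brd4 hairpin (limma, adjusted p threshold 0.05), 4828 upwards and 5001 downwards. At least 2-fold changes were found in 2192 genes, 981 upwards and 1211 downwards. The log2 fold change of Brd4 was −1.62 (SE 0.04, adjusted p = 2.8e-21) and that of Myc −1.95 (SE 0.04, adjusted p = 7.5e-23). Brd3, a paralog of Brd4 (chromosome 2, 27445579 to 27507662), fell by 0.95 (SE 0.05, adjusted p = 3.6e-15), and Brd2, another paralog (chromosome 17, 34112023 to 34122634), rose by 0.26 (SE 0.03, adjusted p = 2.2e-07). Dot1l, the gene of the methyltransferase that SGC0946 inhibits (chromosome 10, 80755206 to 80795461), fell by 0.28 (SE 0.05, adjusted p = 2.1e-05). With all 5 scramble libraries, with and without DMSO, as control, the Dot1l value was −0.07 (adjusted p = 0.687). Hoxa9 (chromosome 6, 52223100 to 52231089) rose by 0.71 (SE 0.04, adjusted p = 9.3e-15), and Meis1 (chromosome 11, 18879817 to 19018985) by 0.44 (SE 0.05, adjusted p = 1.2e-08).

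After S100a9 (log2 fold change 5.15), the largest rises were in Cd74, the invariant chain of MHC class II (5.04, from 5.93 ± 1.23 to 225 ± 6.36 CPM), and in Tspoap1, a binding protein of the mitochondrial translocator protein (4.56, from 92.6 ± 5.32 to 2213 ± 12.9 CPM). S100a8, the partner of S100a9, rose by 4.37, the stefin Stfa2l1 by 3.79 and the mannosyltransferase Pigz by 3.78. Stfa2l1 belongs to a family of near-identical genes, so its reads may belong to a relative. Lysozyme (Lyz2) rose by 3.57, from 79.9 ± 3.2 to 961 ± 76.3 CPM, the complement gene C1qb by 3.51, Zfp36, whose product promotes decay of AU-rich messengers, by 3.50, and the protease cathepsin S (Ctss) by 3.45. The largest fall was in Tnfrsf9, a costimulatory receptor of lymphocytes (−4.46, from 120 ± 22.9 to 4.47 ± 0.939 CPM), although this gene varied between control groups too. Scd1, the stearoyl-CoA desaturase of fatty acid synthesis, fell by 4.41, from 64.6 ± 2.7 to 2.1 ± 0.246 CPM. Further falls were in Stc2, a secreted glycoprotein (−3.97), the Rho regulator Dlc1 (−3.68), the granule protein gene Nkg7 (−3.55) and the autophagy gene Atg9b (−3.27). Ifitm1, an interferon-induced membrane protein, was at −3.06, the adenylate kinase Ak4 at −2.96, the secretory chaperone Fkbp11 at −2.94 and Sash1, a signalling adaptor, at −2.92. The largest adjusted p among these 20 genes was that of C1qb, 8.6e-15.

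Of the 25 gene lists tested, camera called 17, and none of the 17 calls held with an estimated correlation. In this comparison the counts adjusted over the list alone were equal to those over all genes for every list. The MYC list, which holds ribosome assembly and other growth genes, fell in 31 of 31 members, with a median log2 fold change of −1.24 (camera adjusted p = 2.0e-13; adjusted p = 0.051 with an estimated correlation). Nop56, Gnl3 and Mybbp1a, nucleolar genes of this list, fell by 1.65, 1.89 and 1.34. Mitosis genes fell in 29 of 29 members (median −1.70, camera adjusted p = 1.4e-15; adjusted p = 0.077 with an estimated correlation), among them Ube2c by 2.33, Ccnb1 by 2.17 and Cdk1 by 1.74, which drive entry into and exit from mitosis. DNA replication genes fell in 36 of 38 members and 2 did not pass (median −1.40, camera adjusted p = 1.6e-12; adjusted p = 0.201 with an estimated correlation). The helicase subunits Mcm2 and Mcm3 were at −1.57 and −1.53, and Rrm2, which makes deoxynucleotides, at −1.54. Mcm6, a further subunit, fell from 431 to 152 CPM. Cytosolic ribosomal protein genes fell in 53 of 53 members (median −0.80, camera adjusted p = 1.7e-16; adjusted p = 0.190 with an estimated correlation), with Rpl3 at −1.57 and Rps2 at −1.45.

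Cholesterol synthesis genes fell in 25 of 25 members (median −0.87, camera adjusted p = 2.7e-09; adjusted p = 0.051 with an estimated correlation), with Pcsk9, which degrades the LDL receptor, at −2.67 and the synthetic enzymes Fdps and Cyp51 at −1.79 and −1.51. Amino acid response genes, the targets of the stress factor ATF4, fell in 20 of 24 members, 1 rose and 3 did not pass (median −1.45, camera adjusted p = 2.7e-07; adjusted p = 0.267 with an estimated correlation). The serine synthesis genes Phgdh and Psat1 fell by 2.56 and 2.30 and asparagine synthetase (Asns) by 2.06. Glycolysis and hypoxia genes fell in 17 of 22 members, 4 rose and 1 did not pass (camera adjusted p = 0.002; adjusted p = 0.360 with an estimated correlation), among them Pfkp by 1.40 and Ldha by 1.31. Oxidative phosphorylation genes of the nucleus fell in 26 of 32 members, 1 rose and 5 did not pass (camera adjusted p = 5.8e-05; adjusted p = 0.267 with an estimated correlation), with Uqcrc1 at −1.09 and Atp5b falling from 1324 to 661 CPM. Of 11 mitochondrially encoded genes, 8 rose and 3 fell (camera adjusted p = 0.028; adjusted p = 0.502 with an estimated correlation), with mt-Nd6 at 1.12 and mt-Nd5 at 1.04. The list holds the ribosomal RNAs mt-Rnr1 and mt-Rnr2, whose falls (−1.03 and −0.59) were enlarged by scramble replicate 1, at 411 CPM against 113 and 122 and at 891 CPM against 326 and 346. Without that library the list was still called (adjusted p = 0.022). This call ended under quantile normalization (adjusted p = 0.256) and with all 5 scramble libraries as control (adjusted p = 0.056).

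Among myeloid lists, monocyte and macrophage genes rose in 16 of 21 members, 3 fell and 2 did not pass (median 0.97, camera adjusted p = 1.1e-04; adjusted p = 0.190 with an estimated correlation). Adgre1, the macrophage marker F4/80, rose by 2.35, from 222 to 1136 CPM, and Csf2rb, a cytokine receptor chain, by 1.17. Lysosome genes rose in 24 of 27 members, 2 fell and 1 did not pass (median 0.82, camera adjusted p = 3.8e-08; adjusted p = 0.153 with an estimated correlation). Psap, an activator of sphingolipid breakdown, rose by 1.94, the mannosidase Man2b1 by 1.93 and cathepsin D (Ctsd) by 1.63. Neutrophil and granule genes split, with 11 of 24 higher, 10 lower and 3 not passed (camera adjusted p = 0.595; adjusted p = 0.735 with an estimated correlation). S100a9 and S100a8 rose, while the primary granule genes Elane and Mpo, neutrophil elastase and myeloperoxidase, fell by 2.89 and 2.71, from 602 ± 36.3 to 80.3 ± 3.39 and from 350 ± 26.4 to 52.8 ± 3.54 CPM. The size of the Mpo fall depends on the control, since Mpo was also lower in scramble with DMSO than in untreated scramble. MHC class II genes rose in 5 of 8 members, 1 fell and 2 did not pass (camera adjusted p = 0.046; adjusted p = 0.450 with an estimated correlation). H2-Oa and H2-Ob, which modulate peptide loading, rose by 2.08 and 0.93, while the antigen-presenting chain H2-Aa fell by 1.55. Of the 3 measured dendritic cell genes, too few to test as a list, Itgax rose by 1.48 and Clec10a by 0.54, and Tcf4 was at −0.04 (adjusted p = 0.437). The Clec10a call ended with all 5 scramble libraries as control (0.14, adjusted p = 0.639).

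Interferon response genes rose in 18 of 23 members, 3 fell and 2 did not pass (median 0.85, camera adjusted p = 0.002; adjusted p = 0.438 with an estimated correlation), with the antiviral gene Oas2 at 2.86 and the transcription factor Irf7 at 2.40. NF-kB and inflammatory genes rose in 11 of 14 members and 3 fell (camera adjusted p = 0.046; adjusted p = 0.190 with an estimated correlation), with the cytokine Tnf at 2.64 and the chemokine Ccl9 at −0.89. The MHC class II and NF-kB calls each reached only an adjusted p of 0.050, and so ended, without shBRD4 replicate 1, in a fit of the 2 groups alone and under median-of-ratios scaling. They ended under quantile normalization as well (adjusted p = 0.077 and 0.053), and the NF-kB call with DESeq2 (adjusted p = 0.108). Immediate early genes rose in 14 of 20 members, 2 fell and 4 did not pass (median 0.75, camera adjusted p = 0.003; adjusted p = 0.349 with an estimated correlation), with Ier3 at 1.61, Dusp1 at 1.69 and Fosl1 at −2.43. BCL2 family genes rose in 10 of 12 members and 2 fell (median 0.53, camera adjusted p = 0.019; adjusted p = 0.189 with an estimated correlation). The members that rose include Bmf, which promotes cell death, by 2.54, and Bcl2l1 and Mcl1, which oppose it, by 1.14 and 0.88. Histone genes with polyadenylated transcripts rose in 13 of 15 members and 2 fell (median 1.46, camera adjusted p = 0.003; adjusted p = 0.267 with an estimated correlation), with the linker histone Hist1h1c at 2.33 and the variant H2afz at −0.93. Sequences of clustered histone genes resemble each other, so the value of a single member is uncertain.

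The list of MLL-AF9 and DOT1L target genes was not called (13 of 23 rose, 6 fell and 4 did not pass; median 0.39, camera adjusted p = 0.086; adjusted p = 0.360 with an estimated correlation). DESeq2 values (adjusted p = 0.026) and fry (adjusted p = 1.5e-05) called it upwards. Fry called 23 of the 25 lists with the hairpin, so its call says little about this list. The receptor gene Flt3 rose by 1.90 and the transcription factor genes Six1 and Sox4 by 1.14 and 0.91. Stem and progenitor genes were not called either (4 of 14 rose, 8 fell and 2 did not pass; camera adjusted p = 0.683; adjusted p = 0.721 with an estimated correlation). Cd34, a surface marker of progenitors, rose by 2.31, from 472 to 2338 CPM, and Runx1 and Gata2, blood transcription factors, by 1.23 and 0.98, whereas Kit fell by 1.51. The list of p53 target genes split (9 of 18 rose, 8 fell and 1 did not pass; camera adjusted p = 0.582; adjusted p = 0.606 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 1.63, Trp53inp1 at 2.23 and Ccng1 at −0.77. Genes of the BET, elongation and DOT1L complexes split as well (14 of 30 rose, 12 fell and 4 did not pass; camera adjusted p = 0.381; adjusted p = 0.606 with an estimated correlation), with the cyclin gene Ccnt2 at 0.92 and Mllt3, which encodes the AF9 protein, at 1.17. The fusion carries a part of AF9, so reads of the fusion may count towards Mllt3.

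Erythroid genes were not called (1 of 5 rose, 3 fell and 1 did not pass; camera adjusted p = 0.582; adjusted p = 0.656 with an estimated correlation), with the globin Hbb-bt at −0.93 and Gata1 at 1.23. Megakaryocyte and platelet genes were not called (4 of 6 rose, 1 fell and 1 did not pass; camera adjusted p = 0.236; adjusted p = 0.360 with an estimated correlation), with the integrin Itgb3 at 1.76 and thrombospondin (Thbs1) at −2.55. Mast cell, basophil and eosinophil genes were not called (3 of 6 rose, 2 fell and 1 did not pass; camera adjusted p = 0.595; adjusted p = 0.673 with an estimated correlation), with Il1rl1 at 1.51 and Mcpt8 at −1.45. Lists with fewer than 5 measured genes were not tested. The 3 measured T and NK cell genes Nkg7, Lck and Prf1 fell by 3.55, 1.68 and 1.65. Of 4 fibroblast and endothelial genes, Tagln rose by 0.67, Acta2 and Pecam1 fell by 0.41 and 0.16, and Fn1 was at 0.02 (adjusted p = 0.928). The Acta2 call ended with DESeq2 (adjusted p = 0.066). Of the sex-linked genes 1 was measured, Kdm5d, at 0.47 (adjusted p = 0.015), a call that ended without scramble replicate 1 (adjusted p = 0.092), without shBRD4 replicate 1 (adjusted p = 0.140), under quantile normalization (adjusted p = 0.075) and with all 5 scramble libraries as control (adjusted p = 0.066). No B cell gene was measured. As a sign of RNA quality, scramble replicate 1 held more ribosomal and other RNA without poly(A) tails than its partners: Gm42418, which overlaps ribosomal RNA sequence, stood at 8439 CPM there and at 323 and 397 CPM in the other scramble libraries. It was raised to a lesser degree in shBRD4 replicate 1, at 1289 CPM against 404 and 501, as was Lars2, which also overlaps such sequence, at 1160 CPM against 676 and 659.

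The comparison of SGC0946 with DMSO asked which genes depend on DOT1L activity. Meis1 fell from 108 ± 4.33 to 21.8 ± 1.23 CPM and Hoxa9 from 268 ± 2 to 143 ± 3.62 CPM (SD, n = 2 per group), and 18 of the 23 measured MLL-AF9 and DOT1L target genes fell. Granule genes of the neutrophil lineage rose, led by myeloperoxidase (Mpo), from 91.4 ± 9.73 to 2286 ± 54.2 CPM, and neutrophil elastase (Elane), from 459 ± 49.4 to 2918 ± 26.9 CPM. Myc rose from 209 ± 7.09 to 340 ± 4.76 CPM, and 24 of 31 genes of the MYC list rose, Myc among them, although the call of this list ended against untreated scramble (adjusted p = 0.897).

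Of the 11932 genes, 5747 changed with SGC0946 (limma, adjusted p threshold 0.05), 2905 upwards and 2842 downwards. At least 2-fold changes were found in 545 genes, 246 upwards and 299 downwards. Meis1 fell by 2.25 (SE 0.06, adjusted p = 4.9e-20), Hoxa9 fell by 0.90 (SE 0.05, adjusted p = 3.3e-14) and Myc rose by 0.70 (SE 0.05, adjusted p = 1.3e-11). Dot1l rose by 0.48 (SE 0.06, adjusted p = 5.6e-07) and Brd3 by 0.23 (SE 0.06, adjusted p = 0.002). Brd4 and Brd2 each rose by 0.14, with adjusted p = 0.026 and 0.009. The Brd4 call ended without DMSO replicate 1 (adjusted p = 0.171), SGC0946 replicate 1 (adjusted p = 0.066) or SGC0946 replicate 2 (adjusted p = 0.125) and in a fit of the 2 groups alone (adjusted p = 0.056), and the Brd2 call without DMSO replicate 1 (adjusted p = 0.055) or SGC0946 replicate 1 (adjusted p = 0.082). Against the 3 untreated scramble libraries instead of DMSO, Brd4 was at −0.30 and Brd2 at −0.24, while Brd3 was at −0.11 (adjusted p = 0.082) and Dot1l at −0.05 (adjusted p = 0.485). Brd3 was at 0.03 (adjusted p = 0.890) and Dot1l at 0.16 (adjusted p = 0.499) with all 5 scramble libraries as control.

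After Mpo (log2 fold change 4.63), the largest rises were in the chemokine gene Ccl6 (3.76, from 3.75 ± 0.547 to 63.2 ± 4.95 CPM), the chitinase-like gene Chil1 (3.13), the immunoglobulin-family gene Igsf6 (3.08), the small GTPase gene Rab7b (2.91) and the myeloid receptor gene Trem3 (2.88). Slc40a1, the iron exporter ferroportin, rose by 2.86, the inflammation regulator Nlrp12 by 2.73, Elane by 2.67 and Mreg, which takes part in organelle transport, by 2.64. The largest fall was in C2cd4a (−3.63, from 160 ± 32.1 to 11.9 ± 2.31 CPM). The germ cell helicase gene Ddx4 was at −3.52, Kynu, an enzyme of tryptophan breakdown, at −3.47 and F2r, the thrombin receptor, at −3.46. Skida1 and the immediate early transcription factor Egr1 each fell by 3.38, the mast cell protease Cpa3 by 3.22 and the protocadherin Pcdh7 by 3.06, from 298 ± 3.11 to 35 ± 2.55 CPM. Slc45a3 fell by 3.05 and the phosphodiesterase Pde11a by 2.93. The largest adjusted p among these 20 genes was that of Nlrp12, 5.7e-11. Against untreated scramble all 20 kept direction and call with values nearer 0, such as Mpo at 2.70, Chil1 at 1.48, Igsf6 at 0.79, Ddx4 at −1.82, F2r at −1.77 and Egr1 at −1.02. With all 5 scramble libraries as control the calls of Igsf6 (1.71, adjusted p = 0.077) and Egr1 (−1.96, adjusted p = 0.062) ended; Egr1 stood at 19.8 CPM with DMSO and at 3.22 CPM in untreated scramble. Igsf6 and Pcdh7 each overlap 1 other listed gene, with which reads can be shared.

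Camera called 9 of the 25 lists, and 2 of these calls, those of the MLL-AF9 and the neutrophil list, held with an estimated correlation. MLL-AF9 and DOT1L target genes fell in 18 of 23 members, 2 rose and 3 did not pass, with the same counts adjusted over the list alone (median −0.90, camera adjusted p = 1.3e-11; adjusted p = 0.032 with an estimated correlation). Besides Meis1 and Hoxa9, Hoxa10 fell by 2.03, from 422 to 103 CPM, the homeodomain partner Pbx3 by 1.86 and the cofactor gene Eya1 by 2.40. Neutrophil and granule genes rose in 20 of 24 members, 2 fell and 2 did not pass, with 21 higher and 2 lower adjusted over the list alone (median 1.13, camera adjusted p = 7.1e-14; adjusted p = 0.032 with an estimated correlation). Prtn3, the granule protease proteinase 3, rose by 2.58, from 590 to 3529 CPM, and Ngp, a granule protein, by 2.59. Against the untreated scramble libraries, Ngp was at −0.08 (adjusted p = 0.233), and against all 5 at 0.99 (adjusted p = 0.369).

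**Figure D2:**
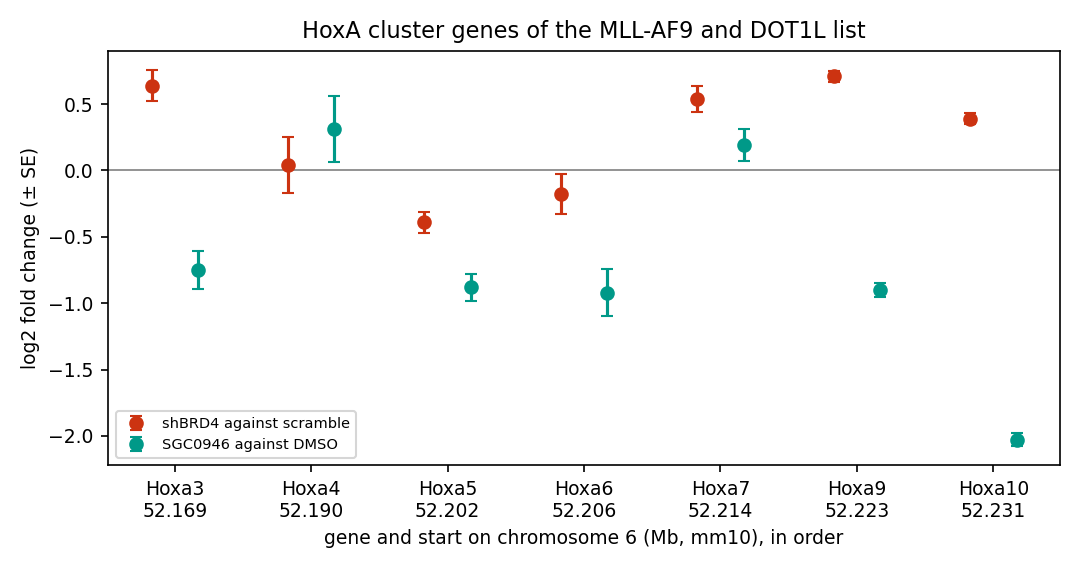
Log2 fold changes (points, with bars of 1 SE) of the 7 HoxA genes of the MLL-AF9 and DOT1L list, in order of their start on chromosome 6 (Mb, mm10), for shBRD4 against scramble and for SGC0946 against DMSO. Hoxa9 and Hoxa10 were at 0.71 and 0.39 with the Brd4 hairpin and at −0.90 and −2.03 with SGC0946. Hoxa10 had a mean of 310 CPM in scramble, 406 CPM in shBRD4 and 422 CPM in scramble with DMSO. Hoxa3 overlaps Hoxa4, Hoxa5 and Hoxa6, so their reads could be shared.

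Genes of the MYC list rose in 24 of 31 members, 1 fell and 6 did not pass, with 25 higher and 1 lower adjusted over the list alone (median 0.27, camera adjusted p = 3.7e-06; adjusted p = 0.179 with an estimated correlation), among them Nolc1 by 0.48 and Phb2 by 0.41. This list was lower with DMSO than in untreated scramble in 23 of 31 members, and its call ended against untreated scramble (adjusted p = 0.897). DNA replication genes rose in 25 of 38 members and 13 did not pass, with 25 adjusted over the list alone (median 0.24, camera adjusted p = 9.2e-06; adjusted p = 0.591 with an estimated correlation), with the licensing factor Cdt1 at 0.83 and Rrm2 at 0.57. Mitosis genes rose in 11 of 29 members and 18 did not pass, with 10 adjusted over the list alone (median 0.13, camera adjusted p = 0.009; adjusted p = 0.591 with an estimated correlation), with Aurkb at 0.41 and Cdk1 at 0.28. The mitosis call ended without DMSO replicate 2 (adjusted p = 0.104) and without SGC0946 replicate 1 (adjusted p = 0.054). Lysosome genes fell in 16 of 27 members, 4 rose and 7 did not pass, with 17 lower and 4 higher adjusted over the list alone (median −0.19, camera adjusted p = 0.006; adjusted p = 0.591 with an estimated correlation), with Ctsl at −0.64 and Neu1 at 0.68. Glycolysis and hypoxia genes fell in 16 of 22 members, 2 rose and 4 did not pass, with 16 and 2 adjusted over the list alone (median −0.39, camera adjusted p = 2.9e-05; adjusted p = 0.591 with an estimated correlation), with Bnip3, a hypoxia-induced mitophagy gene, at −1.45 and Egln3, a prolyl hydroxylase, falling from 528 to 265 CPM. Immediate early genes fell in 10 of 20 members, 4 rose and 6 did not pass, with 10 and 4 adjusted over the list alone (median −0.35, camera adjusted p = 0.027; adjusted p = 0.591 with an estimated correlation), with Egr1 at −3.38 and Atf3 at −1.61. This call ended without DMSO replicate 2 (adjusted p = 0.104), with genes of at least 5 CPM on average (adjusted p = 0.127) and with DESeq2 (adjusted p = 0.104). Mast cell, basophil and eosinophil genes fell in 5 of 6 members and 1 rose, with 5 and 1 adjusted over the list alone (median −0.90, camera adjusted p = 0.006; adjusted p = 0.179 with an estimated correlation). Cpa3 fell by 3.22, the histamine-producing enzyme Hdc by 1.15 and Mcpt8 by 1.28, while Siglecf rose by 1.63. Against untreated scramble Hdc turned to 0.74 (adjusted p = 6.8e-13). With all 5 scramble libraries as control the calls of Hdc (−0.02, adjusted p = 0.986), Mcpt8 (−0.65, adjusted p = 0.143), Bnip3 (−0.78, adjusted p = 0.118), Ctsl (−0.29, adjusted p = 0.269) and Nolc1 (0.27, adjusted p = 0.097) ended.

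The remaining lists were not called by camera. Stem and progenitor genes split (6 of 14 rose, 5 fell, 3 did not pass; camera adjusted p = 0.336), with Prom1 at 2.59, Angpt1 at −2.76, Gata2 at −1.86 and Cd34 falling from 432 to 152 CPM. This list was called downwards with DESeq2 (adjusted p = 0.003), against untreated scramble (adjusted p = 0.002) and with all 5 scramble libraries as control (adjusted p = 0.036). Prom1 stood at 1.55 CPM with DMSO, 14.3 with SGC0946 and 11.4 in untreated scramble, and its call ended with all 5 as control (1.22, adjusted p = 0.197). Monocyte and macrophage genes (8 of 21 rose, 3 fell, 10 did not pass; camera adjusted p = 0.238) held Csf2ra at 1.76, Cd14 at 1.43 and Adgre1 at −1.79. MHC class II genes (1 of 8 rose, 4 fell, 3 did not pass; camera adjusted p = 0.081) held H2-Oa at −0.95 and Cd74 at −0.71. This list was called downwards with genes of at least 5 CPM on average (adjusted p = 0.023), without SGC0946 replicate 2 (adjusted p = 0.031) and with all 5 scramble libraries as control (adjusted p = 0.036). Interferon response genes (2 of 23 rose, 8 fell, 13 did not pass; camera adjusted p = 0.068) held Zbp1 at −1.40 and Ifit2 at 1.19. This list was called downwards in a fit of the 2 groups alone (adjusted p = 0.035), without SGC0946 replicate 2 (adjusted p = 0.047) and, barely, without DMSO replicate 1 (adjusted p = 0.050). BCL2 family genes (3 of 12 rose, 4 fell, 5 did not pass; camera adjusted p = 0.222) held Bcl2 at −1.06 and Bcl2l1 at −0.97. The p53 targets (2 of 18 rose, 7 fell, 9 did not pass; camera adjusted p = 0.311) held Sesn1 at −0.55, which turned to 0.26 against untreated scramble (adjusted p = 0.001). NF-kB and inflammatory genes (4 of 14 rose, 7 fell, 3 did not pass; camera adjusted p = 0.850) had a median of −0.30 and a mean of 0.05, with Ccl9 at 1.23 and Ccl3 at −1.21. Complex genes around BET proteins and DOT1L (8 of 30 rose, 7 fell, 15 did not pass; camera adjusted p = 0.962) held the elongation factor Ell2 at −0.60.

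Histone genes (6 of 15 rose, 2 fell, 7 did not pass; camera adjusted p = 0.222) held H2afx at 0.71, which turned to −0.14 against untreated scramble (adjusted p = 0.026). Cholesterol synthesis genes (9 of 25 rose, 4 fell, 12 did not pass; camera adjusted p = 0.376) held Fdps at 0.38 and Cyp51 at −0.53, which turned to 0.34 against untreated scramble (adjusted p = 1.4e-06). ATF4 targets (10 of 24 rose, 5 fell, 9 did not pass; camera adjusted p = 0.222) held Cth at 1.63 and Trib3 at −0.96. Oxidative phosphorylation genes (12 of 32 rose, 1 fell, 19 did not pass; camera adjusted p = 0.079) held Uqcrc1 at 0.46; this list was called upwards without SGC0946 replicate 2 (adjusted p = 0.047). Ribosomal protein genes (11 of 53 rose, 2 fell, 40 did not pass, against 7 and 2 adjusted over the list alone; camera adjusted p = 0.222) held Rps2 at 0.22. Mitochondrially encoded genes (5 of 11 rose, 6 did not pass; camera adjusted p = 0.068) held mt-Co1 at 0.38, whose call ended under quantile normalization (0.17, adjusted p = 0.348). This list was called upwards without DMSO replicate 1 (adjusted p = 6.8e-04), without SGC0946 replicate 2 (adjusted p = 0.018) and with replicate number as a block (adjusted p = 0.026). Erythroid genes (1 of 5 rose, 2 fell, 2 did not pass; camera adjusted p = 0.490) held Hbb-bt at −1.53, which was at 0.20 against untreated scramble (adjusted p = 0.209), and Car2 at 1.20. Megakaryocyte genes (1 of 6 rose, 2 fell, 3 did not pass; camera adjusted p = 0.555) held Itga2b at −2.61 and Thbs1 at 2.27. Adjusted over the list alone, a further stem cell gene and a further megakaryocyte gene passed downwards. Apart from the ribosomal protein list, the counts of the other uncalled lists were the same. Against DMSO all 3 dendritic cell genes fell (Tcf4 by 1.47, Itgax by 1.06, Clec10a by 0.39), but Clec10a turned to 0.60 against untreated scramble (adjusted p = 3.7e-06) and to 0.21 against all 5 (adjusted p = 0.648). Of the T and NK cell genes Nkg7 rose by 2.37 and Prf1 fell by 2.03. Among fibroblast and endothelial genes Acta2 rose by 1.08 and Pecam1 fell by 0.41, and Kdm5d was at 0.07 (adjusted p = 0.797).

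With the untreated scramble libraries as control, a choice made after the data were seen, 7020 genes changed with SGC0946. Of the 4009 genes called against both controls, 3408 had the same direction and 601 the opposite one. The MLL-AF9 list (median −0.67, camera adjusted p = 8.4e-09) and the neutrophil list (median 0.43, camera adjusted p = 1.8e-04) were called in the same directions, whereas the MYC (adjusted p = 0.897), mitosis (0.170), glycolysis (0.777) and mast cell (0.490) calls ended. Against untreated scramble the ribosomal protein (7.5e-13), cholesterol (7.3e-12) and oxidative phosphorylation (4.1e-05) lists were called upwards. The stem and progenitor list and that of the complexes around BET proteins and DOT1L were called downwards (both 0.002). These 5 lists had no call against DMSO, and 5 of the 9 calls against DMSO held. With all 5 scramble libraries without compound as control, the count was 3253 genes; the glycolysis (0.098) and mast cell (0.135) calls ended, and the cholesterol (0.001), oxidative phosphorylation (2.7e-04) and ribosomal protein (5.0e-06) lists were called upwards.

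**Figure D3:**
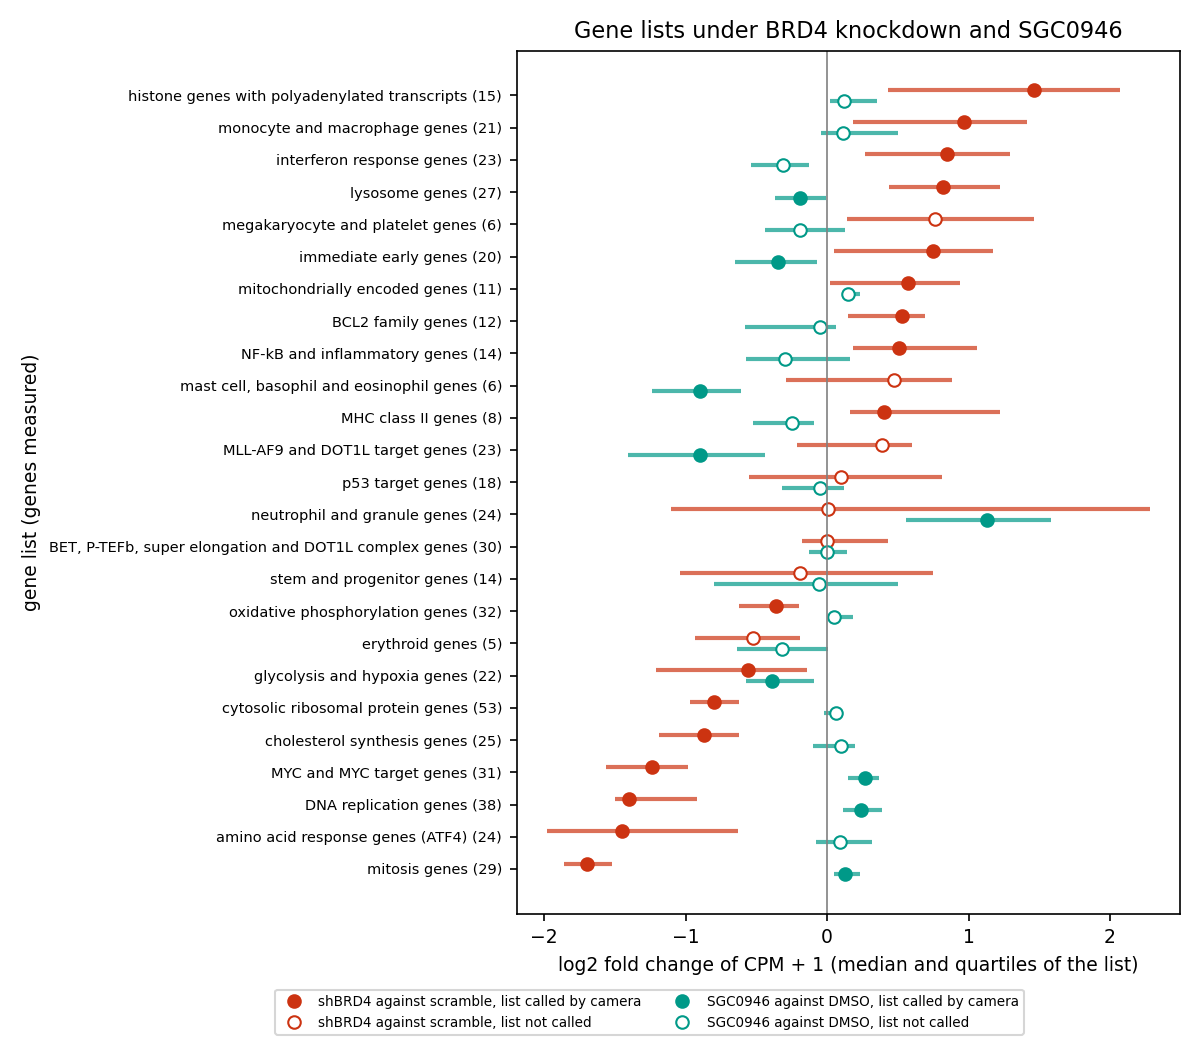
Log2 fold changes of the 25 tested gene lists, with points at the median and lines between the quartiles of each list, for shBRD4 against scramble and SGC0946 against DMSO; filled points mark lists called by camera. The MYC list was at −1.24 with the Brd4 hairpin and at 0.27 with SGC0946, and the MLL-AF9 list at 0.39 and −0.90.

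The difference between the effects of the Brd4 hairpin and of SGC0946 was tested in the same model, to ask whether loss of BRD4 and inhibition of DOT1L act on the same genes. Myc fell with the hairpin and rose with the compound, a difference of −2.65 on the log2 scale (SE 0.06, adjusted p = 3.9e-21). Hoxa9 and Meis1 rose with the hairpin and fell with the compound, with differences of 1.61 (SE 0.06, adjusted p = 1.6e-17) and 2.69 (SE 0.08, adjusted p = 1.1e-19). The hairpin side of Meis1 depends on the control, since shBRD4 libraries (118, 118 and 115 CPM) lay near scramble with DMSO (111 and 105 CPM). The granule genes Mpo and Elane fell with the hairpin and rose with the compound, with differences of −7.34 (SE 0.09, adjusted p = 3.2e-27) and −5.56 (SE 0.08, adjusted p = 6.6e-26). The sizes depend on the control, most of all for Mpo, which was lower with DMSO than in untreated scramble. Against untreated scramble, Mpo and Elane rose with SGC0946 by 2.70 and 2.28, instead of 4.63 and 2.67 against DMSO. The fall of Mpo with the hairpin is likewise smaller when set against scramble with DMSO. Each effect was measured against its own control, 3 libraries per group for the hairpin and 2 for the compound.

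The effects differed in 9139 of the 11932 genes (limma, adjusted p threshold 0.05), 4510 with a higher value for the hairpin and 4629 with a lower one. Of the 4928 genes called in both comparisons, 3308 changed in opposite directions and 1620 in the same direction. Genes that fell with the hairpin and rose with the compound numbered 1741, where independent lists would share 1218, and genes that rose with the hairpin and fell with the compound numbered 1567, where independent lists would share 1150. Genes up in both numbered 770 (1175 if independent) and genes down in both 850 (1191 if independent). Among genes changed at least 2-fold in both, each combination exceeded the number for independent lists: 70 fell and rose (25 if independent), 55 rose and fell (25), 29 rose in both (20) and 44 fell in both (30). Across genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was −0.19 and the Spearman correlation −0.25. The comparisons share no control library.

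**Figure D4:**
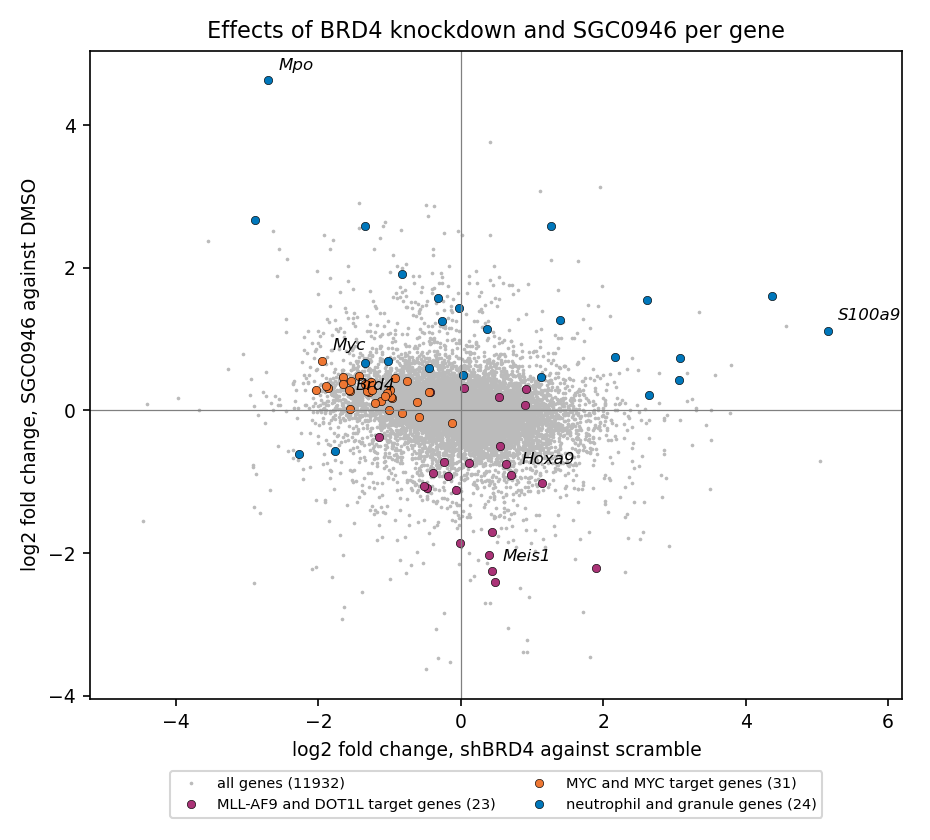
Log2 fold change of each of the 11932 genes with the Brd4 hairpin against scramble (horizontal axis) and with SGC0946 against DMSO (vertical axis), with 3 gene lists in colour. Myc was at −1.95 and 0.70, Meis1 at 0.44 and −2.25, Mpo at −2.71 and 4.63 and S100a9 at 5.15 and 1.12.

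The largest differences towards the hairpin were in Cd74 (5.76), the thrombin receptor F2r (5.27), the kinase gene Camk1d (4.84), Zfp36 (4.60) and the aldo-keto reductase Akr1c12 (4.55), a gene with close relatives. Those towards the compound were in Mpo, Nkg7 (−5.92), Elane, the clotting factor gene F13a1 (−5.14) and Thbs1 (−4.83). Among the other genes fixed beforehand, the difference was −1.76 for Brd4 (SE 0.06), −1.18 for Brd3 (SE 0.08) and −0.76 for Dot1l (SE 0.08). For Brd2 it was 0.12 (SE 0.06, adjusted p = 0.049), a call that ended without any of 8 libraries taken singly, with adjusted p between 0.054 and 0.162, and with array weights (adjusted p = 0.066).

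Camera on the difference was chosen after the data were seen. By this test, the MLL-AF9 and DOT1L list was higher for the hairpin in 20 of 23 members and lower in 2 (median difference 0.84, camera adjusted p = 1.5e-06; adjusted p = 0.053 with an estimated correlation), with Flt3 at 4.11 and Hoxa10 at 2.42. The hairpin side of Hoxa10 depends on the control, with a mean of 406 CPM in shBRD4 and 422 CPM in scramble with DMSO. The list was also higher with DMSO than in untreated scramble (median 0.28), which enters the difference. The MYC list was lower in 30 of 31 members (median −1.52, camera adjusted p = 4.0e-14; adjusted p = 0.053 with an estimated correlation), mitosis genes in 29 of 29 (median −1.81, camera adjusted p = 8.4e-16; adjusted p = 0.053 with an estimated correlation) and DNA replication genes in 38 of 38 (median −1.62, camera adjusted p = 1.1e-13; adjusted p = 0.196 with an estimated correlation). Ribosomal protein genes were lower in 53 of 53 members (camera adjusted p = 9.1e-16; adjusted p = 0.196 with an estimated correlation), cholesterol synthesis genes in 24 of 25 (camera adjusted p = 3.2e-08; adjusted p = 0.053 with an estimated correlation) and ATF4 targets in 21 of 24 (camera adjusted p = 4.4e-07; adjusted p = 0.277 with an estimated correlation). Lysosome genes were higher in 23 of 27 members and lower in 1 (camera adjusted p = 1.2e-08; adjusted p = 0.105 with an estimated correlation), and immediate early genes higher in 15 of 20 and lower in 2 (camera adjusted p = 0.001; adjusted p = 0.277 with an estimated correlation). Neutrophil and granule genes were not called (8 of 24 higher, 14 lower; camera adjusted p = 0.068; adjusted p = 0.372 with an estimated correlation). For the lists of this paragraph the counts adjusted over the list alone were the same.

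The comparison of the control groups asked how far scramble cells with DMSO (n = 2) lay from untreated scramble cells (n = 3). Tnfrsf9, which fell with the Brd4 hairpin, was higher with DMSO, at 1264 ± 82.2 against 120 ± 22.9 CPM (SD). Angptl4, an inhibitor of lipoprotein lipase, was lower, at 15.5 ± 1.71 against 192 ± 14.2 CPM, and the granule gene Ngp was lower, at 15.6 ± 0.407 against 105 ± 8.5 CPM. Cholesterol synthesis genes were higher with DMSO in 22 of 25 members, with Hmgcs1, Msmo1 and Hmgcr at 1.32, 1.30 and 1.16.

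Of the 11932 genes, 6728 differed (limma, adjusted p threshold 0.05), 3402 higher and 3326 lower with DMSO, and 301 differed at least 2-fold. The 2-fold count depended on the method, with 130 for a pseudocount of 5 CPM, 556 for 0.1 CPM, 581 with edgeR and 540 with DESeq2. The other large differences were in the immune checkpoint receptor Pdcd1 (4.14), the protease inhibitor Serpine1 (3.61), Dhrs9 (3.02) and Akr1c18 (3.01), all higher, and in Serpinb9g (−2.77), the interleukin antagonist Il1rn (−2.62) and the kinase gene Src (−2.41), all lower. Brd4, Brd2, Brd3 and Dot1l were at −0.44, −0.38, −0.35 and −0.53, while Hoxa9 and Meis1 were higher by 0.23 and 0.32. Myc was at −0.11 (adjusted p = 0.045), a call that ended without any of the 3 scramble libraries (adjusted p = 0.067, 0.071 and 0.103) and without DMSO replicate 1 (adjusted p = 0.268). It also ended with quantile normalization and with the 2 groups alone (both adjusted p = 0.063), with array weights (adjusted p = 0.076) and with DESeq2 (adjusted p = 0.057). The cholesterol list was called with both kinds of correlation (camera adjusted p = 1.2e-11; adjusted p = 0.048 with an estimated correlation). Ribosomal protein genes were higher in 44 of 53 members, or 45 adjusted over the list alone (camera adjusted p = 1.2e-10; adjusted p = 0.382 with an estimated correlation). Neutrophil genes were lower in 16 of 24 and higher in 2, or 16 and 3 adjusted over the list alone (camera adjusted p = 1.7e-06; adjusted p = 0.216 with an estimated correlation), with Mpo at −1.93. Genes of the MYC list were lower in 23 of 31, or 25 adjusted over the list alone (camera adjusted p = 1.7e-05; adjusted p = 0.267 with an estimated correlation). MLL-AF9 targets were higher in 14 of 23, or 16 adjusted over the list alone (camera adjusted p = 0.004; adjusted p = 0.281 with an estimated correlation), and glycolysis genes in 17 of 22 (camera adjusted p = 2.9e-05; adjusted p = 0.382 with an estimated correlation). Complex genes around BET proteins and DOT1L were lower in 20 of 30 (camera adjusted p = 0.002; adjusted p = 0.281 with an estimated correlation). Oxidative phosphorylation genes were higher in 17 of 32 (camera adjusted p = 0.012; adjusted p = 0.604 with an estimated correlation) and DNA replication genes in 19 of 38 (camera adjusted p = 0.041; adjusted p = 0.776 with an estimated correlation). The vehicle, the experiment and any library batch cannot be told apart in this comparison.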

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

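All tests in this part were chosen after the results they measure were seen, except the comparison of the effects of the Brd4 hairpin and SGC0946 gene by gene. Groups of 2 or 3 libraries were not tested for a single library far from its group. Scramble replicate 1 nevertheless stood apart in its reads, with a chi-square per gene of 15.92 and 15.43 against its partners. These gave 1.74 between them, and pairs within other groups 1.54 to 3.51. A few genes with many reads can carry this average, such as Gm42418 at 8439 CPM in that library against 323 and 397. The correlation of its log2 values with its partners, 0.9961 and 0.9965, was near the 0.9964 of the DMSO pair.

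The following results stood out because the effect of the Brd4 hairpin differed from that of SGC0946 in a test of the difference itself (limma, log2 scale). The difference was −1.76 for Brd4 (adjusted p = 8.6e-18), the target of the hairpin. For its paralogs it was −1.18 for Brd3 (adjusted p = 7.3e-13) and 0.12 for Brd2 (adjusted p = 0.049), the latter lost without any of 8 single libraries (adjusted p = 0.054 to 0.162). It was −0.76 for Dot1l (adjusted p = 5.3e-09). The Dot1l and Brd3 values depend on the control, since their rises with SGC0946 (0.48 and 0.23) became −0.05 and −0.11 against untreated scramble (adjusted p = 0.485 and 0.082). Myc differed by −2.65 (adjusted p = 3.9e-21), Hoxa9 by 1.61 (adjusted p = 1.6e-17) and Meis1 by 2.69 (adjusted p = 1.1e-19). Among lists called in both comparisons in opposite directions, the median difference was −1.52 for MYC target genes (camera adjusted p = 4.0e-14) and −1.62 for DNA replication genes (camera adjusted p = 1.1e-13). It was −1.81 for mitosis genes (camera adjusted p = 8.4e-16), 0.99 for lysosome genes (camera adjusted p = 1.2e-08) and 0.96 for immediate early genes (camera adjusted p = 0.001). With an estimated correlation the adjusted p of these lists lay at 0.053 for MYC and mitosis genes, 0.196 for DNA replication, 0.105 for lysosome and 0.277 for immediate early genes. The calls of these lists within each comparison were lost in that way too (adjusted p = 0.051 to 0.349 for the hairpin and 0.179 to 0.591 for SGC0946). Those of the MYC and mitosis lists for SGC0946 also ended against untreated scramble (adjusted p = 0.897 and 0.170).

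The 6 libraries of the hairpin comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 9829 genes and was the 1 split with as many. The highest count of the others was 0. Every other split mixes shBRD4 and scramble libraries in both arms, so the hairpin effect enters the spread within arms. Their low counts follow from this, and the splits cannot decide on chance.

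MLL-AF9 and DOT1L target genes were higher with the Brd4 hairpin than with SGC0946 in 20 of 23 members. The difference between the control groups enters this pattern. The list was higher with DMSO than in untreated scramble in 14 of 23 members and lower in 5. Its median there was 0.28 (camera adjusted p = 0.004, and 0.281 with an estimated correlation). Against untreated scramble it still fell with SGC0946 (median −0.67, camera adjusted p = 8.4e-09). That comparison also holds the vehicle and the experiment. The size of the pattern depends on the control. The lower quartile of the differences of the effects stayed above 0 under all 3 scalings, at 0.52 or more. These scalings put the median difference of all genes between 0.00 and 0.02. Shifts that small could not bring the quartile to 0, so this result does not decide on scaling. A single library is argued against, since that quartile was at least 0.45 without each of the 10 libraries. Less RNA per cell under the hairpin might raise these genes in CPM without a rise per cell, and a fall of 1.63-fold would cancel the rise of Hoxa9 with the hairpin, but not its fall with SGC0946 (−0.90). The tables hold no spike-in or cell count, so for the hairpin side of the pattern this and an effect of the hairpin on the genes cannot be told apart.

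The untreated and DMSO scramble groups differed in 6728 genes. Scramble replicate 1 held more ribosomal RNA than its partners (Lars2, which overlaps ribosomal sequence, at 5777 against 648 and 680 CPM), yet 6358 genes were called without it, which argues against this carry-over as the whole cause. Less carry-over of RNA without poly(A) tails in the DMSO libraries might lower such RNA. Hist1h1a, Hist1h1b, Hist1h1d and Hist1h1e were lower with DMSO (−1.23, −1.08, −1.14 and −1.23). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were higher (1.23 and 0.98). As the only cause, carry-over would leave the cholesterol list on both sides of 0, yet the lower quartile of that list was 0.33. A part of carry-over in the difference stays open. Of the 15 genes of the fixed histone list 3 were higher and 4 lower. That list was chosen for polyadenylated transcripts but also holds Hist1h1e, so its counts do not decide on carry-over. DMSO itself and any other difference between the experiments cannot be told apart, since 0 groups of either experiment received the vehicle of the other.

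Neutrophil and granule genes were higher with SGC0946 than with DMSO in 20 of 24 members, and 16 of the 24 were lower and 2 higher with DMSO than in untreated cells (camera adjusted p = 1.7e-06; adjusted p = 0.216 with an estimated correlation). Against untreated scramble the list was also called (camera adjusted p = 1.8e-04, preset correlation), with 17 members higher and 4 lower. Its median was 0.43 and its lower quartile 0.03 there, against a median of 1.13 with DMSO as control. That comparison also holds the vehicle and the experiment, so it cannot decide whether a low DMSO level is the whole cause. A single library is argued against, with lower quartiles of at least 0.53 without each of 4 libraries. The lower quartile was at least 0.52 under the other scalings. These left the median of all genes at 0.01 and 0.02, a shift too small to decide on scaling. An effect of the compound on the neutrophil programme may be kept as a hypothesis, found and tested on the same data. Its size depends on the control.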

How the results depend on the processing

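The gene model, its alternatives and the gene lists were set before the data were examined; the untreated control for SGC0946, the use of all 5 scramble libraries as control for lists and single genes, and the 2-fold counts under each alternative were chosen after seeing the data. Apart from the 2-fold requirement and the pooled control named below, the alternatives set beforehand gave 8463 to 9999 genes for the hairpin (main 9829) and 4666 to 5952 for SGC0946 (main 5747); the untreated control gave 7020. Leaving out 1 library at a time gave 9492 to 9557 genes for the hairpin, 4666 to 5456 for SGC0946, 5478 to 6358 between the controls and 8689 to 9012 for the difference; a lone library was assumed to vary like the other groups. It gave 15 to 17 lists for the hairpin and 7 to 13 for SGC0946, a Brd4 value of −1.66 to −1.59, and a correlation of the effects of −0.20 to −0.18. Counts of 2-fold changes were then 2135 to 2253 for the hairpin and 541 to 590 for SGC0946. With replicate number as a block the counts were 9888, 5952, 6601 and 9211; the labels do not say that equal numbers pair libraries. The counts with no filter were identical because all genes pass it, so that alternative tests nothing, and a fit of 2 groups alone was not run for the difference, which needs all 4. Requiring a 2-fold change left 2192 genes for the hairpin and 545 for SGC0946 by construction; with a pseudocount of 5 CPM, which shrinks folds of low genes, these were 1273 and 276. They rose to 2741 and 763 with 0.1 CPM, 2796 and 774 with edgeR, and 2790 and 721 with DESeq2. An estimated correlation left 0 called lists for the hairpin and 2 for SGC0946. Fry, which does not compare a list with other genes, called 23 for the hairpin and 18 for SGC0946. Fry turned the stem and progenitor list upwards with the hairpin (adjusted p = 0.005) and the NF-kB list upwards with SGC0946 (adjusted p = 1.6e-04). With all 5 scramble libraries as control for SGC0946, which pools groups that differ, 3253 genes were called, and the log2 fold changes became −0.13 for Brd4, −0.09 for Brd2, 0.21 for Clec10a and for Insig1, 0.01 for Epor and 0.19 for Itgb3, all of the opposite sign. With the untreated control the sign also turned for Brd4 (−0.30), Brd2 (−0.24), Brd3 (−0.11), Dot1l (−0.05), Mybbp1a (−0.20), Ngp (−0.08), Clec10a (0.60), Plk1 (−0.03), Cdc20 (−0.07), Sesn1 (0.26), H2afx (−0.14), Cyp51 (0.34), Insig1 (0.63), Hbb-bt (0.20), Epor (0.45), Itgb3 (0.56), Ppbp (1.59), Hdc (0.74) and Tagln (−0.53); apart from the change of control libraries, the cause was not tested. Over all alternatives, list results stayed on their side of the threshold 943 times (13 of these changed direction without a call in either), 34 gained a call, 46 lost it and the 2 above turned; for named genes the numbers were 9158 (18 changed sign without a call), 15, 88 and 25. Depth limits genes near the floor of 0.234 to 0.297 CPM, the value of 3 reads, whose folds depend on the pseudocount.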

Other observations

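The families, genes of the HoxA cluster and RNA species in this part were chosen after the data were seen; the tests of gene length and of transcripts of 1 exon were set before their results were seen.

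Of the families below, some of whose members are also in the fixed lists, only the first held its call with an estimated correlation for the Brd4 hairpin. Aminoacyl-tRNA synthetase genes, whose products load amino acids onto tRNA, fell in 30 of 37 members and rose in 2 (median −0.68, camera adjusted p = 3.5e-07; adjusted p = 0.011 with an estimated correlation). Translation initiation factor genes fell in 44 of 51 members and rose in 2 (median −0.59, camera adjusted p = 5.9e-09; adjusted p = 0.054 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 64 of 76 members and rose in 6 (median −0.55, camera adjusted p = 1.0e-07; adjusted p = 0.054 with an estimated correlation). All 8 CCT chaperonin genes, which serve actin and tubulin folding, fell (median −0.93, camera adjusted p = 2.5e-05; adjusted p = 0.108 with an estimated correlation). Nucleoporin genes fell in 17 of 19 members and rose in 1 (median −0.69, camera adjusted p = 2.5e-05; adjusted p = 0.054 with an estimated correlation), and proteasome genes fell in 37 of 39 and rose in 2 (median −0.42, camera adjusted p = 1.2e-06; adjusted p = 0.086 with an estimated correlation). Small nucleolar RNA host genes, among them Gas5 (−1.57) and Snhg5 (−1.71), fell in 7 of 8 members and rose in 1 (median −1.30, camera adjusted p = 0.002; adjusted p = 0.054 with an estimated correlation).

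With SGC0946 the synthetase genes rose in 20 of 37 members (median 0.15, camera adjusted p = 0.002; adjusted p = 0.060 with an estimated correlation), the host genes in 4 of 8 (camera adjusted p = 0.025; adjusted p = 0.167 with an estimated correlation) and the mitochondrial ribosomal protein genes in 25 of 76, with 1 lower (camera adjusted p = 0.018; adjusted p = 0.423 with an estimated correlation). Nucleoporin genes rose in 9 of 19 members and fell in 2 (camera adjusted p = 0.025; adjusted p = 0.423 with an estimated correlation). The chaperonin (adjusted p = 0.263), initiation factor (adjusted p = 0.124), proteasome (adjusted p = 0.378) and clustered histone genes (adjusted p = 0.263) were not called. In the HoxA cluster on chromosome 6, Hoxa11 fell with the hairpin (−0.90) and with SGC0946 (−1.81), as did Hoxa5 (−0.39 and −0.88) and Hoxa11os (−0.36 and −0.42), which overlaps Hoxa11. Hoxa3, Hoxa9 and Hoxa10 rose with the hairpin and fell with SGC0946. The rise of Hoxa10 depends on the control, since it stood at 310 CPM in scramble, 406 CPM with the hairpin and 422 CPM with DMSO. Hoxa3 overlaps Hoxa5, so their reads could be shared. The nuclear RNAs Neat1 and Malat1 rose with the hairpin by 3.08 and 2.37 on the log2 scale. Neat1 was also higher with DMSO than in untreated scramble, by 1.51 (limma, adjusted p = 9.7e-14), while Malat1 was lower there (−0.58).

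Histone genes of the Hist clusters rose with the hairpin in 17 of 18 members and fell in 1 (median 1.34, camera adjusted p = 6.4e-05, and 0.104 with an estimated correlation). Many members were low in scramble, such as Hist2h3c2 at 0.189 and Hist2h4 at 0.322 CPM, where few reads set the fold. Others were higher, such as Hist1h1c (58.7 to 300 CPM) and Hist2h2be (8.9 to 45.3 CPM). Hist1h1d was highest in shBRD4 replicate 1 (10.2 against 7.31 and 5.21 CPM), the library with raised Gm42418. A hypothesis was that transcripts of 1 exon rise as a class. The 156 other protein-coding genes of 1 exon had a median of 0.21, above 99.9% of 10000 random lists of like expression, whose values from the lowest to the highest 2.5% ran from −0.19 to 0.13; 73 rose and 45 fell. This is consistent with a shift of the class that may add to the rise of the histone genes, although it is smaller than theirs. Another hypothesis was that long genes fall more under loss of BRD4. Across 10969 protein-coding genes the Spearman correlation of gene span and log2 fold change was 0.04 (bootstrap SE 0.009, 200 draws), which argues against it. The same correlation was −0.12 with SGC0946, a comparison for which no such hypothesis was set.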
